A study of Oryza sativa with 3 samples.

How the data were processed

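Small RNA libraries were made from spores of the rice cultivar Guichao No.2, isolated at 3 stages on a sucrose gradient, with total RNA extracted by a column kit and a standard Illumina preparation, per the labels' protocols. There is 1 library for uninucleate microspores (UNM), 1 for bicellular pollen (BCP) and 1 for tricellular pollen (TCP), and the labels describe small RNAs of 13 to 40 nt in UNM and of 13 to 41 nt in BCP and TCP. Bowtie 1.1.2 is named per the submitters' processing notes. The reference, the genome build, the trimming and the mapping options are not given in the sources used here.

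Each deposited list has 3 columns, the anticodon of the tRNA, the fragment sequence and a count, per the file headers. The deposited count of UNM and BCP is a whole number of reads per distinct sequence, with no normalization, and only sequences read at least once are listed. The count column the authors deposited for TCP was not taken as reads, since its 8633 numbers lie between 1 and 28, sum to 24515 and repeat along nested fragments of the same tRNA. It was used only for which sequences are listed, so the comparisons of reads with TCP that had been planned were not made, nor were top sequences of TCP ranked. The lists hold sequences of 10 to 40 nt in UNM and TCP and of 10 to 39 nt in BCP. Sequences shorter than 13 nt were kept in the totals, with 234 reads in UNM and 127 in BCP. The total of all small RNAs in a library was not used here, so each share is of the listed tRNA-derived reads, and a share cannot tell a rise of one fragment from a fall of the rest.

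Sequences were joined across the lists by exact identity. The amino acid was taken from the anticodon by the standard genetic code. The anticodon label differed between lists for 207 sequences, which held 1.12% of UNM and 2.20% of BCP reads, and the amino acid for 20 sequences, which were kept as ambiguous and held 0.020% and 0.004% of reads. The anticodon among Ala isoacceptors also changes with fragment length, since short fragments match several of them, so shares are described by amino acid and not by single anticodon. The initiator tRNA is not separated from other tRNA-Met by the labels.

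Shares are given with exact Clopper-Pearson 95% intervals and ratios of shares with exact conditional binomial 95% intervals. A 0 in one library was set to 3 counts for a ratio, which corresponds to 0.000437% of reads in UNM and 6.05e-05% in BCP. Counts of 1 and 2 were used as they are, so a sequence with 1 read can rank beyond a sequence with 0. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Single sequences were compared from 50 summed reads on and counted as higher or lower when the ratio was at least 2-fold and its interval excluded 1. Medians of groups of at least 5 sequences were set among 10000 random lists of the same size matched on level in 10 bins. No test between stages was made, since each has 1 library. The calls were tested on simulated data for BCP against UNM, with Poisson counts drawn at the mean share of both libraries and at their real depths. Of 1715 sequences that passed the minimum, 94.0% of those simulated 3-fold higher and 94.1% of those 3-fold lower were called. All (100%) of those changed 8-fold in either direction were called, as were 1.41% of the unchanged ones. Each changed set was simulated with 50 sequences. All 50 of either higher set passed the minimum, but only 34 of those 3-fold lower and 19 of those 8-fold lower did. The percentages are of those that passed, so falls were missed more often than rises. These rates cover counting error only and not variation between libraries.

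The lists give no position on the tRNA, and a rule for that case was added after the data were seen. A fragment was taken as 5′ when the motif of mature positions 8 to 14 (U, purine, any base, pyrimidine, any 2 bases, A) lies where a start at mature positions 1 to 3 puts it. Fragments of tRNAs without this motif, and fragments too short to hold it, stay unplaced. A motif that lies 1 base further than a start at position 1 puts it is also outside the rule. Trailer and internal fragments could not be separated. Plastid-type fragments were found by exact match to 23 rice plastid tRNA sequences written down from general knowledge after the data were seen, under the right amino acid label. Of these, 22 had a match of at least 20 nt and 17 had at least 50 summed reads. Mitochondrial and nuclear origin was not scored. No genome was used. A gene table of rice assembly ASM3414082v1 served only to count annotated nuclear tRNA genes per anticodon.

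The named items, the tests, the size classes and the settings listed first below were fixed before the data were examined. The text names the 10 most abundant sequences of UNM and of BCP, the 5 largest rises and the 5 largest falls of a sequence, with sequences of the same amino acid and the same first 13 nt reduced to the most abundant one and a 0 set to the floor, and the 5 amino acids with the largest rise and the 5 with the largest fall among those with at least 1% of reads in either library (4 had a lower share). How to reduce sequences was settled after a ranking had been seen. The other sequences, anticodons and plastid tRNAs named were chosen after their values were seen.

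The other settings tried were median-of-ratios size factors, a filter of 10 reads, thinning BCP to the UNM total, leaving out the 10 most abundant sequences, counting distinct sequences, dropping or splitting ambiguous sequences, common lengths of 10 to 37 nt, exact position 1, a minimum of 200 reads, a threshold of 4-fold and sums per anticodon and class. The alternatives added after the data were seen were plastid matches of at least 18 nt, fragments of at most 33 nt and leaving out Asp fragments. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9 were used.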

Results

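Small RNAs derived from tRNAs were profiled in spores of the rice (Oryza sativa) cultivar Guichao No.2 at 3 stages of male gametophyte development, with 1 library per stage. Uninucleate microspores (UNM) are the haploid spores before the asymmetric division, bicellular pollen (BCP) holds a vegetative and a generative cell, and tricellular pollen (TCP) holds the vegetative cell and a pair of sperm cells. Each deposited list gives distinct fragment sequences, the anticodon of the parent tRNA and a number per sequence. The UNM list held 5477 distinct sequences and 686685 reads. The BCP list held 14717 distinct sequences and 4958412 reads, 7.22 times as many reads as UNM. The TCP list held 8633 distinct sequences, but its numbers did not exceed 28 and were not used as read counts, so levels were compared between UNM and BCP and TCP entered only through which sequences it lists. All shares below are percentages of the tRNA-derived reads listed for a library, since the total of all small RNAs was not used here. With 1 library per stage the differences have no replicate check, and the exact 95% intervals in parentheses cover counting error only. The lists carry no genomic positions, so fragments are identified by sequence and anticodon.

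The identity of the parent tRNAs was compared between the microspore and the bicellular stage. Fragments of tRNA-Ala made up 47.1% of UNM reads (47.0 to 47.2) and 13.9% of BCP reads (13.8 to 13.9), a log2 ratio of -1.77. Fragments of tRNA-Asp made up 1.23% of UNM reads (1.21 to 1.26) and 36.3% of BCP reads (36.2 to 36.3), 29.4-fold higher in BCP (28.8 to 30.02). Fragments of tRNA-Ser fell from 20.4% to 5.71%, and those of tRNA-Glu took the same share in both libraries, 16.0% and 16.0%. Of the 20 amino acid groups, 6 were at least 2-fold higher in BCP, 3 were at least 2-fold lower and 11 lay within 2-fold. With sequences kept only from 10 reads on in at least 1 library, which admits more of the deeper BCP library, 9 groups were at least 2-fold higher. Besides Asp, the higher groups were His, Phe, Pro, Leu and Tyr. His rose from 1.07% to 7.55%, 7.04-fold (6.88 to 7.21), Phe 5.18-fold (4.93 to 5.45) to 1.20%, Pro 4.62-fold (4.44 to 4.80) to 1.78%, and Leu 3.05-fold (2.96 to 3.13) to 2.27%. Besides Ala and Ser, the lower group was Arg, which fell from 1.01% to 0.475%, 2.13-fold (2.08 to 2.19). Fragments of tRNA-Met, a label under which the initiator tRNA is not separated, had 1.83% in UNM and 1.61% in BCP, a log2 ratio of -0.19. Gly lay at 6.39% in UNM and 8.67% in BCP. Of 48 anticodons with at least 50 summed reads, 17 were at least 2-fold higher and 10 at least 2-fold lower in BCP. The anticodon label among Ala isoacceptors changes with fragment length, so these counts partly reflect length.

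**Figure D1:**
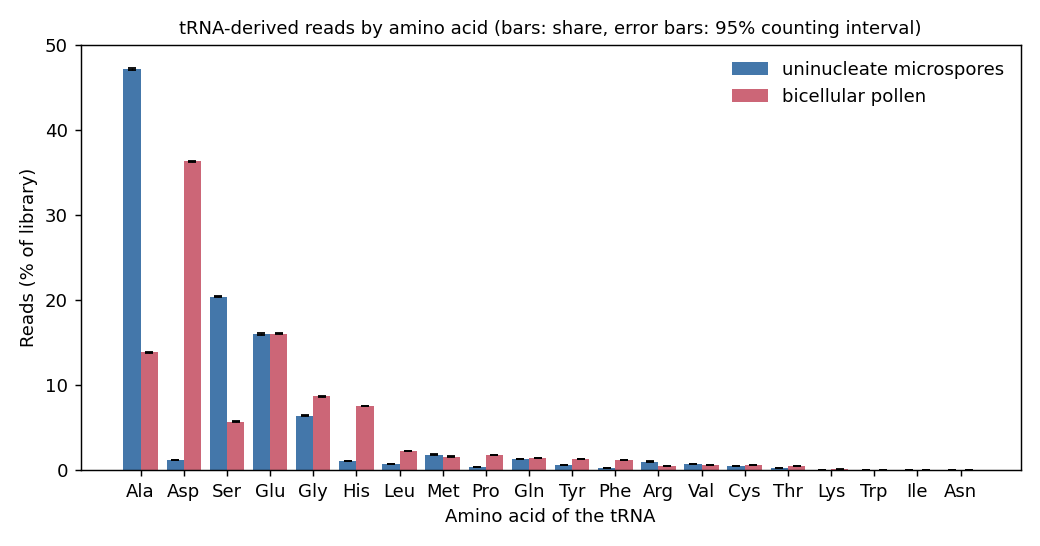
Share of tRNA-derived reads (y axis, % of the library) by amino acid of the parent tRNA (x axis) in the UNM and BCP libraries, with exact 95% counting intervals as error bars. Ala leads in UNM at 47.1% and Asp in BCP at 36.3%, while Glu stands at 16.0% in both.

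Shares within a library sum to its total, and without Asp fragments the log2 ratio of each other group was 0.63 higher: Ala then stood at -1.13, Gly and Thr joined the groups at least 2-fold higher, and Arg left the lower ones. Without the 10 most abundant sequences the Asp log2 ratio was 3.15 in place of 4.88, and counted by distinct sequences instead of reads it was -0.0038. Counted that way Ser, Leu and Phe had log2 ratios of 0.06, -0.05 and -0.52, while Ala (-0.55), Arg (-0.25) and His (0.25) kept their direction with smaller values.

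Among the most abundant fragments, mostly placed at the first base of the mature tRNA, shares went in both directions. In the Asp group, the 32-nt fragment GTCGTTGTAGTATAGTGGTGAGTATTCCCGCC had 955 reads in UNM and 677135 in BCP, 98.2-fold higher (92.2 to 105), and it was the most abundant sequence of the BCP library at 13.7% of its reads. Its 33-nt version, longer by a single T, rose 34.2-fold (32.4 to 36.1) to 6.74% of BCP reads, and its 35-nt version 65.2-fold (59.9 to 71.0) to 5.21%. A 14-nt fragment with the same start, GTCGTTGTAGTATA, went from 131 reads to 230728, 244-fold higher (206 to 292). In the Ala group, the 14-nt fragment GGGGATGTAGCTCA led the UNM library with 11.3% of reads and had 0.612% in BCP, 18.5-fold lower (18.2 to 18.7). The 15-nt version GGGGATGTAGCTCAA was 5.83-fold lower in BCP (5.76 to 5.91), and the 16-nt version GGGGATGTAGCTCAAA went from 9.06% to 4.74%, 1.91-fold lower (1.90 to 1.93). A related Ala fragment, GGGGACGTAGCTCATA, had 3.27% in UNM and 4.37% in BCP. The 13-nt Ala fragment GGGGATGTAGCTC was 57.0-fold lower in BCP (55.1 to 59.1), and GAGGTACGGGGATC, a 14-nt Ala fragment whose place on the tRNA was not assigned, was 115-fold lower (110 to 122). In the Ser group, the 18-nt fragment GGATGGATGTCTGAGCGG fell from 9.05% to 0.462%, 19.6-fold (19.3 to 19.9), and its 19-nt version 30.01-fold (29.3 to 30.7). Among Glu fragments the 16-nt TCCGTTGTAGTCTAGC had 10.4% in UNM and 5.94% in BCP, while the 33-nt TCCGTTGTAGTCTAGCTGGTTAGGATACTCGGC rose 4.93-fold (4.79 to 5.09) to 3.21%. The Gly fragment GCGTCTGTAGTCCAACGG, of 18 nt, fell 9.73-fold (9.50 to 9.97). The 10 most abundant sequences held 64.8% of UNM reads (64.6 to 64.9) and 52.0% of BCP reads (51.9 to 52.0), and 3 sequences were among the 10 most abundant in both libraries.

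The size of the fragments differed between the stages. In UNM, 93.4% of reads were at most 20 nt long and 4.04% (3.99 to 4.08) at least 30 nt, whereas in BCP 41.3% were at most 20 nt and 50.8% (50.7 to 50.8) at least 30 nt. The class of 30 to 34 nt rose 15.1-fold (14.9 to 15.3), from 2.68% to 40.5%, the class of 25 to 29 nt 6.26-fold (6.11 to 6.42) and that of 35 to 41 nt 7.62-fold (7.47 to 7.78). The class of 18 to 20 nt fell from 28.7% to 6.61%, a log2 ratio of -2.12, and that of 13 to 17 nt had 64.6% in UNM and 34.7% in BCP, a log2 ratio of -0.90. The classes of 21 to 22 nt and 23 to 24 nt, the sizes of most plant microRNAs and small interfering RNAs, held under 1% of reads each in both libraries, at 0.998% and 0.907% for the former and 0.600% and 0.873% for the latter. The most frequent length was 16 nt in both libraries, with 25.5% of UNM and 18.6% of BCP reads, and both had a maximum at 14 nt, with 19.5% and 6.23%. Further maxima above 1% lay at 18 nt (14.1%) and 33 nt (1.21%) in UNM and at 19 nt (3.09%), 26 nt (2.89%), 32 nt (17.1%) and 35 nt (8.66%) in BCP.

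**Figure D2:**
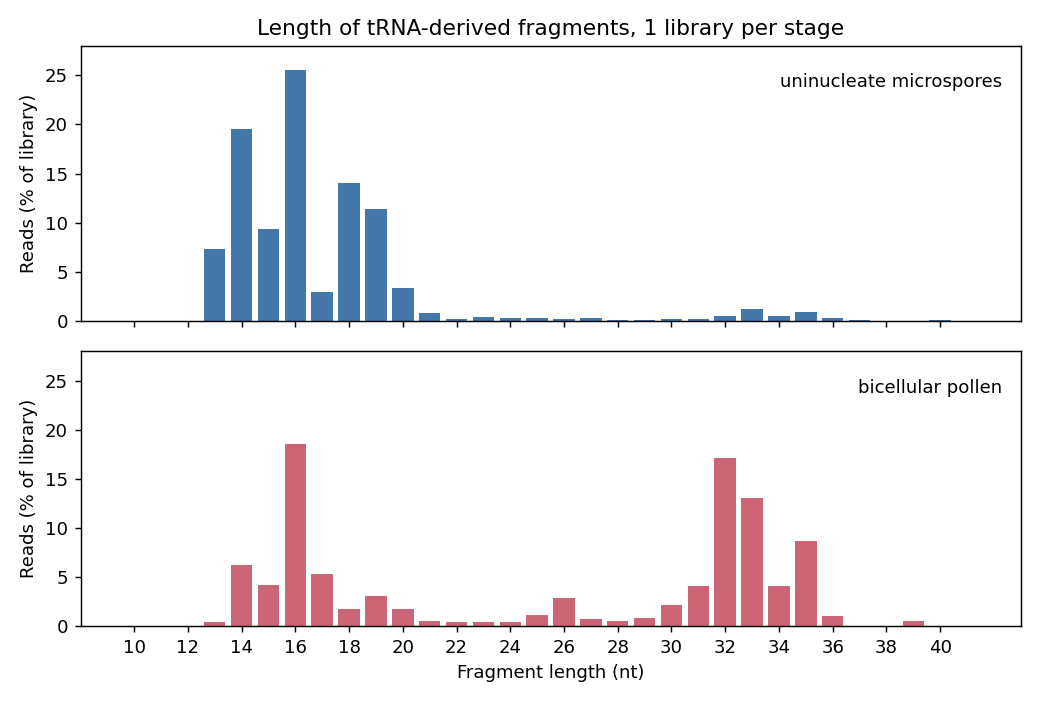
Share of tRNA-derived reads (y axis, % of the library) at each fragment length (x axis, nt) in UNM and BCP, 1 library each. In UNM the reads lie at 20 nt and below (93.4%), and in BCP 50.8% of reads are at least 30 nt long.

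The longer fragments were not a matter of Asp alone: the share of fragments of at least 30 nt was higher in BCP in 20 of 20 amino acid groups, with counting intervals that did not overlap. Within Asp it went from 40.3% to 74.3%, within His from 14.9% to 62.3%, within Leu from 6.45% to 85.1%, within Gly from 17.4% to 53.0% and within Ser from 0.955% to 22.5%. Ala kept short fragments in both libraries, with 0.038% and 1.96% of its reads at 30 nt or more and modal lengths of 14 and 16 nt. Without Asp fragments the share of long reads was 3.58% in UNM and 37.4% in BCP. With the BCP long shares weighted by the amino acid composition of UNM, 20.5% of reads were long. With the UNM long shares weighted by the composition of BCP, 19.9% were. Amino acid composition alone thus did not give the whole difference. A shift between tRNAs of the same amino acid counts as length in this weighting. A Leu family of 5′ fragments with the same first 13 bases had 160 reads in UNM and 89312 in BCP. It was 97.5% and 99.4% long. In a Glu family the long reads instead went from 7.30% to 34.3%. Weighting by such families was not run, so the part of length was not separated from composition within amino acids. Of the UNM sequences with at least 50 reads, 2 of 341 with at most 33 nt were absent from the BCP list, against 13 of 31 with 34 to 37 nt, so values at 34 nt and above depend on what the lists hold. Among fragments of at most 33 nt only, the log2 ratio of those of 30 to 33 nt was 4.26, while the full class of 30 to 34 nt had 3.91 with all lengths. In that setting Leu turned to -0.48, and Tyr and Arg were no longer 2-fold different.

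**Figure D3:**
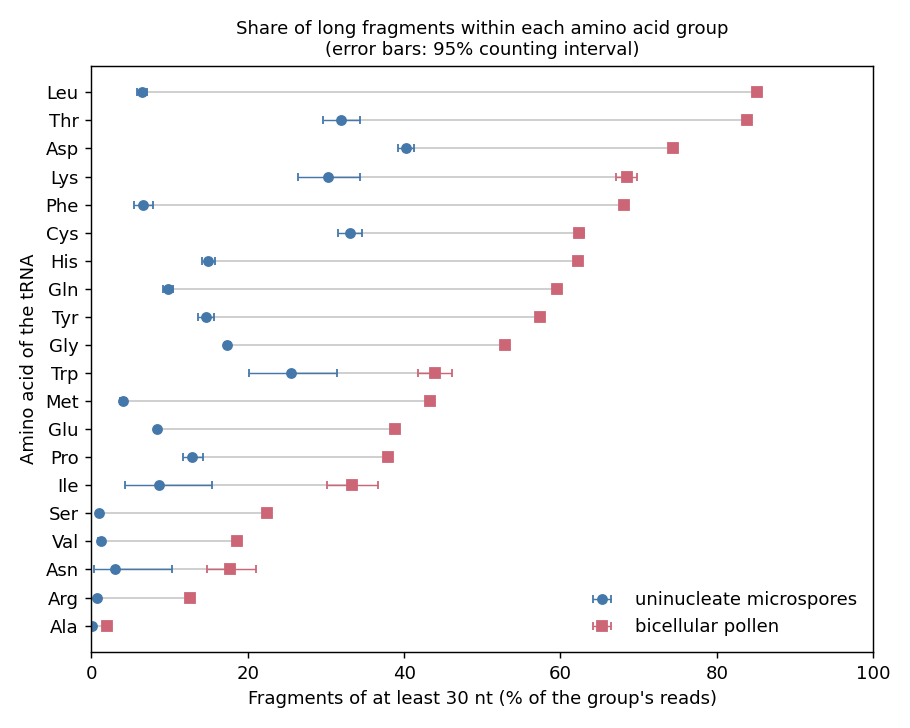
Share of reads of at least 30 nt (x axis, % of the reads of the group) for each amino acid (y axis) in UNM and BCP, with exact 95% counting intervals as error bars. The BCP value lies to the right of the UNM value in 20 of 20 groups, from 1.96% for Ala to 85.1% for Leu in BCP.

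Where the fragments lie on the tRNA was read from the sequence, since the lists give no position. Fragments that begin at mature positions 1 to 3 made up 81.9% of UNM reads (81.8 to 82.0) and 87.5% of BCP reads (87.5 to 87.5), and most began at position 1, with 80.8% and 83.0%. The placement held for short and long reads alike, at 81.6% of UNM and 82.4% of BCP reads of at most 20 nt and at 87.4% and 92.7% of those of at least 30 nt. Fragments that end in CCA, the last bases of a mature tRNA, made up 0.162% of UNM and 0.287% of BCP reads, a log2 ratio of 0.83. Most of these reads, 77.9% in UNM and 91.1% in BCP, are placed as 5′ fragments, so they are not counted as 3′ ends, and those that are not placed as 5′ had 0.036% and 0.026%, a log2 ratio of -0.48, which was 0.15 without Asp fragments. Fragments that hold the 5-base T-arm motif (UUC, purine, A) anywhere in the read rose from 0.589% to 3.67%, 6.23-fold (6.04 to 6.43). The motif also occurs in 5′ fragments, so this is not a measure of 3′-side fragments. The 17-nt trnD-GUC fragment named below, placed as 5′, holds it. That fragment had 737 of the 4043 UNM reads with the motif and 85687 of the 181856 BCP reads. Without Asp fragments the log2 ratio of the share of 5′ fragments was -0.02 in place of 0.10. The motif ends at position 14, so the rule cannot place a 13-nt fragment that starts at position 1. Reads of 13 nt made up 7.36% of UNM and 0.416% of BCP reads. The unplaced 13-nt Ala fragment named above alone held 4.12% and 0.072%. The rise in the shares of 5′ fragments and of position 1 may therefore come from the rule, and a real rise was not shown. Reads whose motif lies 1 base further than a start at position 1 puts it are also outside the rule. They made up 0.688% of UNM and 2.79% of BCP reads, so unlike the 13-nt reads they were higher in BCP.

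The nucleotide at the 5′ end was examined because plant Argonaute proteins differ in the base they prefer there. Reads that start with G dominated both libraries, at 77.7% in UNM and 77.8% in BCP. Those that start with U had 16.99% and 13.7%, those with A 4.02% and 3.90%, and those with C rose from 1.30% to 4.59%, 3.54-fold (3.47 to 3.62). Reads that start with at least 4 G, which are mostly Ala fragments, fell from 41.6% to 13.9%, a log2 ratio of -1.58. Without Asp fragments that log2 ratio was -0.96, the log2 ratios of A and U turned to 0.58 and 0.31, and that of G was -0.24 in place of 0.0028, so the equal share of G depends on Asp.

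Fragments with the sequence of plastid tRNAs were counted as a marker of plastid-bearing material. They made up 2.47% of UNM reads (2.43 to 2.51) and 12.7% of BCP reads (12.7 to 12.7), 5.14-fold higher in BCP (5.06 to 5.22). Of 17 plastid-type tRNAs with at least 50 summed reads, 14 were at least 2-fold higher in BCP, 1 was lower and 2 lay within 2-fold. Fragments of trnF-GAA were 38.7-fold higher (33.03 to 45.8), those of trnL-CAA 37.8-fold (34.004 to 42.1) and those of trnE-UUC 33.9-fold (29.7 to 38.9). The rise of trnF-GAA lay in its fragments of at least 30 nt (log2 ratio 5.99), while those of at most 20 nt were lower (-1.01). The most abundant was trnH-GUG, at 0.801% of UNM and 3.37% of BCP reads, followed in BCP by trnD-GUC at 2.32%. The 35-nt trnL-CAA fragment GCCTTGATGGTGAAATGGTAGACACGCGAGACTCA went from 152 reads to 86261, 78.6-fold higher (67.0 to 92.8), and the 17-nt trnD-GUC fragment GGGATTGTAGTTCAATT from 737 to 85687, 16.1-fold (14.97 to 17.3). The exception was trnC-GCA, which had 0.195% in UNM and 0.069% in BCP, a log2 ratio of -1.49. Plastid-type fragments accounted for most of the reads of tRNA-Leu, tRNA-Phe and tRNA-Tyr in BCP. Of 2.27% for Leu, 1.91% came from trnL-CAA, of 1.20% for Phe, 0.852% from trnF-GAA, and of 1.35% for Tyr, 1.06% from trnY-GUA. Such sequences can also come from mitochondrial or nuclear copies of plastid tRNAs, which the lists do not separate. Without Asp fragments the log2 ratio of the plastid-type share was 2.99 against 2.36 with all fragments.

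**Figure D4:**
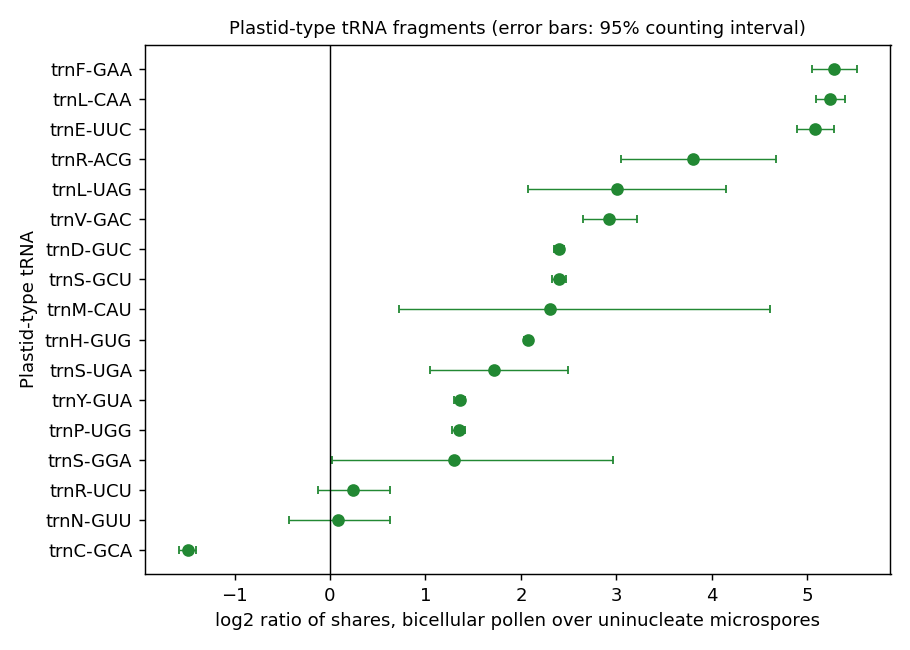
log2 ratio of the share in BCP over that in UNM (x axis) for the 17 plastid-type tRNAs with at least 50 summed reads (y axis), with exact 95% counting intervals as error bars. Of these, 14 were at least 2-fold higher in BCP and trnC-GCA lies at -1.49.

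Single fragments were compared to see which sequences carried these shifts. Of 1794 sequences with at least 50 summed reads, 1224 were at least 2-fold higher in BCP, 308 at least 2-fold lower and 262 neither, counted where the interval of the ratio excludes 1. The minimum on summed reads admits more sequences of the deeper library: with BCP thinned to the UNM total, 435 of 767 sequences were higher and 231 lower, so 65.3% of the called sequences were higher against 79.9% at full depth. Of the tested sequences, 418 had no read in UNM and 17 none in BCP. With the minimum of 50 reads and the floor of 3 counts, the former always count as higher and the latter as lower. Those calls were thus fixed by the rule. By length, 377 of 395 sequences of 30 to 34 nt were higher and 2 lower, with a median log2 ratio of 3.24 that lay above all 10000 random lists of the same size and level, whereas among 573 sequences of 13 to 17 nt, 236 were higher and 199 lower. By amino acid, 56 of 96 Ala sequences were lower and 18 higher, with a median of -1.61 below all 10000 random lists. Of the 74 Asp sequences 62 were higher and 3 lower, with a median of 3.13 above all of them, and 117 of 134 His and 104 of 111 Pro sequences were higher. The median over all tested sequences was 2.01, so a positive median is the usual case. In the groups Ser and Arg, whose shares fell, 126 of 202 Ser sequences were higher and 39 lower, with a median of 1.86 at percentile 7.84 of the random lists, and 39 of 82 Arg sequences were higher and 16 lower, with a median of 1.11 below all 10000. Nested fragments of 1 tRNA are not independent, so the random lists only describe these libraries.

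The largest rises by the naming rule, whose reduction by start was settled after a ranking had been seen, were of fragments almost unread in UNM. They were the 24-nt trnV-GAC fragment AGGGATATAACTCAGCGGTAGAGT with 1 read in UNM and 2211 in BCP, 306-fold (54.9 to 12100), a 34-nt fragment of tRNA-Ser with anticodon GGA with 1 and 2102, 291-fold (52.2 to 11503), a 35-nt fragment of tRNA-Tyr with 3 and 6008, 277-fold (94.9 to 1345), a 22-nt fragment of tRNA-Gly with anticodon GCC with 1 and 1911, 265-fold (47.4 to 10459), and a 32-nt fragment of tRNA-Met with 3 and 5330, 246-fold (84.1 to 1193). Without the reduction by start the largest rise was that of a 39-nt trnH-GUG fragment with 0 reads in UNM and 16548 in BCP, 764-fold at the floor of 3 counts and at least 621-fold by the exact limit, but the UNM list holds no sequence of 39 nt. The largest falls by the same rule, which keeps the most abundant sequence of each start, were of fragments of 13 or 15 nt. Without that reduction the largest fall was that of a 35-nt Gly fragment, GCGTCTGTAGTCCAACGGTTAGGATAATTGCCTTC, with 2885 reads in UNM and 0 in BCP, 6944-fold lower at the floor of 3 counts and at least 5644-fold by the exact limit. It is among the 13 of 31 UNM sequences of 34 to 37 nt that are absent from the BCP list. By the rule, GTCCGAAAGGGCG, of tRNA-Leu with anticodon TAG, went from 1282 reads in UNM to 2 in BCP, 4629-fold lower (1279 to 38260), and the Leu fragment GTCAAGATGGCCGAG from 1183 to 12, 712-fold (406 to 1382). The others were GGACATTGGACTC of tRNA-Gln from 217 reads to 1, 1567-fold (278 to 62171), TCTCGGTGGAACC of tRNA-Gln from 204 to 3, 491-fold (166 to 2401), and CCGGCAATGGAAC of tRNA-Glu from 328 to 5, 474-fold (201 to 1469).

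The sequences listed at the 3 stages overlapped in part. Of 18424 distinct sequences, 2690 were listed at all 3 stages, 1237 only in UNM, 7324 only in BCP and 2150 only in TCP. Of the 1012 UNM sequences with at least 10 reads, 92.3% were also listed in BCP (90.5 to 93.9) and 86.0% in TCP (83.7 to 88.1). Of the 3819 BCP sequences with at least 10 reads, 56.4% were also listed in UNM (54.8 to 58.0) and 81.2% in TCP (79.9 to 82.4). With BCP thinned to the UNM total, 81.0% of the UNM sequences were listed in BCP and 77.3% of the BCP sequences in UNM. The share of BCP sequences also listed in TCP rose with their reads in BCP, from 16.8% of those with 1 read to 98.3% of those with at least 10001. In TCP, 25.6% of the distinct sequences were at least 30 nt long, against 14.6% in UNM and 19.9% in BCP, and plastid-type sequences were 19.8% of the list against 9.53% and 15.2%. Asp took 2.62% of the TCP sequences, against 3.20% in UNM and 3.19% in BCP, and Ala 2.86% against 5.28% and 3.60%. These are shares of listed sequences and not of reads, and they depend on depth, which is unknown for TCP.

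**Figure D5:**
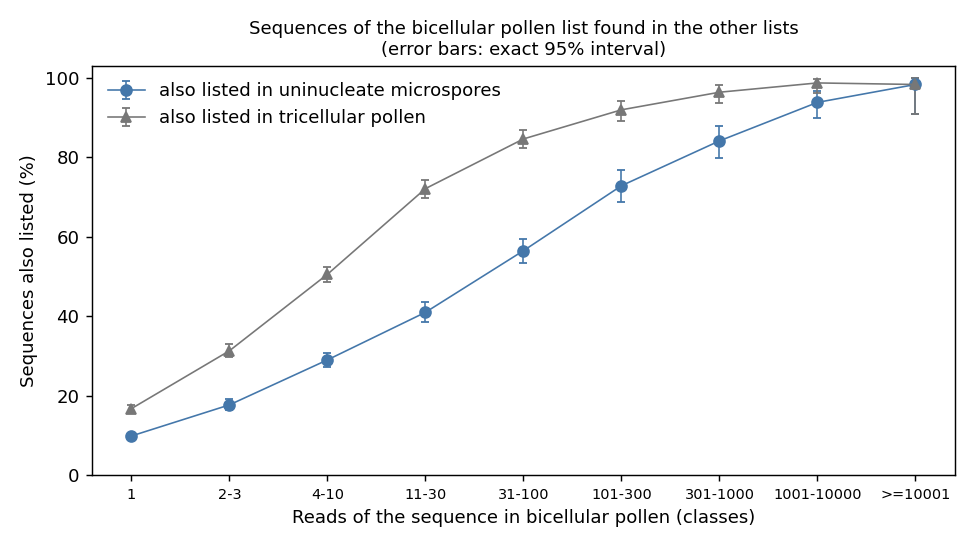
Percentage of BCP sequences also listed in UNM and in TCP (y axis), by class of reads of the sequence in BCP (x axis), with exact 95% intervals as error bars. The share listed in TCP goes from 16.8% at 1 read to 98.3% at 10001 reads or more.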

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

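The tests of the TCP numbers below were all chosen after the numbers had been seen. The TCP list drew attention as data outside the comparisons of reads: 2150 of its sequences are in neither other list, and the largest number in its column is 28.

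The column may hold another unit than reads. Of 235 pairs of TCP fragments that differ by a single base at the 3′ end, both with numbers of at least 10, 51.9% had exactly the same number, against 7.40% if they were Poisson counts and against 1.78% of such pairs in UNM and 0.998% in BCP. A shallow read count of a library like BCP is argued against by the length of the list: BCP reads thinned to the TCP sum of 24515 gave at most 1423 distinct sequences in 100 draws, and TCP lists 8633. Whether the number counts the tRNA gene loci that match a fragment cannot be told from the gene numbers per anticodon. The highest number per anticodon rose with the number of annotated nuclear tRNA genes over 48 anticodons. The anticodons share tRNA families and are not independent replicates. Spearman rho was 0.66 (permutation p 1e-05, the smallest the permutations can give) and Pearson r was 0.60 (permutation p 3e-05, both 2-sided). Without the 2 anticodons farthest from the median gene number rho was 0.65 and r was 0.61. The number was above the annotated gene number for 12 of the 48 anticodons (28 against 19 for AGC, 27 against 18 for GTA), but a short fragment can match genes of several anticodons and the assembly of the lists is not known. Abundant fragments can carry low numbers, such as the 18-nt Gly fragment GCGTCTGTAGTCCAACGG with 11664 reads in BCP and the number 1 in TCP, so which unit it is stays open, and no biological explanation was tested.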

How the results depend on the processing

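The alternatives with fragments of at most 33 nt, without Asp fragments and with plastid matches of at least 18 nt were chosen after the data were seen. The direction of Ala, of the 13 to 17 nt and 30 to 34 nt classes, of the GGGG start and of the plastid-type share held in every alternative run for them, and causes were not tested except where noted. Values are log2 ratios of BCP over UNM unless a percentage or a count is named.

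Counting distinct sequences gave Asp -0.0038, Ala -0.55, Cys -0.47, Gln -0.22, Leu -0.052, Met 0.43, Phe -0.52, Ser 0.062, Thr -0.073 and Val 0.14, all of the opposite sign to the reads except Ala.

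Leaving out Asp, which raises the other shares by construction, gave Ala -1.13, 13 to 17 nt -0.59, 30 to 34 nt 3.65, the GGGG start -0.96 and plastid-type 2.99, and the top 10 then held 65.6% of UNM and 41.3% of BCP reads. The sign turned for 5′ fragments (-0.019), position 1 (-0.13), fragments that end in CCA and are not placed as 5′ (0.15), unplaced fragments (0.082), Met (0.45), Val (0.33), 21 to 22 nt (0.49), A (0.58) and U (0.31), and G moved from 0.0028 to -0.24.

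Without the 10 most abundant sequences the values were Ala -2.25, Asp 3.15, 5′ fragments 0.11, 13 to 17 nt -0.64, 30 to 34 nt 3.55, the GGGG start -1.66 and plastid-type 2.60, and the next 10 held 52.8% of UNM and 26.6% of BCP reads. Met (0.054), position 1 (-0.032), 21 to 22 nt (0.10) and A (0.19) turned, and G moved to -0.13.

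With fragments of at most 33 nt they were Ala -1.57, Asp 4.99, 5′ fragments 0.10, 13 to 17 nt -0.70, 30 to 33 nt 4.26, the GGGG start -1.38 and plastid-type 2.10, the top 10 held 66.0% and 55.9%, and 94.98% of UNM sequences were listed in BCP. Gln (-0.12), Leu (-0.48), Lys (-0.47), 21 to 22 nt (0.059) and A (0.043) turned.

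With common lengths they were Ala -1.76, 5′ fragments 0.10, 13 to 17 nt -0.89, the GGGG start -1.57 and plastid-type 2.33, the BCP top 10 held 52.3%, 82.8% of BCP sequences were listed in TCP, and Lys turned to -0.24.

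Depth moved the lists by construction: thinned BCP held 6620 sequences, 435 of them higher, a top 10 of 52.0%, 81.0% of UNM sequences listed in BCP, and 77.3% and 93.2% of BCP sequences listed in UNM and TCP. The filter of 10 reads left 2402 UNM and 3988 BCP sequences, a top 10 of 65.3% and 52.2%, and 5′ fragments at 0.091, and 9 amino acid groups at least 2-fold higher in place of 6, the added ones being Asn (4.66), Ile (1.93) and Thr (1.12). A minimum of 200 reads left 577 higher and 147 lower sequences, and sums per anticodon and class 42 higher and 19 lower units of 96. Exact position 1 gave 0.038 for 5′ fragments, size factors 0.089 for them and -0.90 for 13 to 17 nt, and longer plastid matches 2.60. No paired analysis was possible because each stage has 1 library.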

Other observations

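All tests in this part were chosen after the result they bear on had been seen, and the fragment families named here were chosen after their values were seen.

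The 5′ fragments were also summed by their first 13 bases. The Asp family GTCGTTGTAGTAT held 0.713% of UNM and 33.4% of BCP reads, with modal lengths of 33 and 32 nt, and 67.9% of its UNM reads and 80.3% of its BCP reads were at least 30 nt long, so it was long at both stages and differed mainly in its share. The His family GTGGCTGTAGTTT, with 80.7% long reads in both libraries, went from 0.103% to 3.22%. The Glu family TCCGTTGTAGTCT instead kept a similar share, 14.3% and 10.1%, while its long reads went from 7.30% to 34.3%. The Gly families GCGTTTGTAGTCC and GCGTCTGTAGTCC changed their modal length from 18 to 26 nt. The Ser families split: GGATGGATGTCTG fell from 15.7% to 1.59% and GTGGTCGTGCCGG from 2.14% to 0.024%, while GGAGAGATGGCTG rose from 0.219% to 1.12% and GTCGATATGTCCG from 0.155% to 1.31%.

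Of 13 plastid-type tRNAs with at least 50 summed reads in both size classes, 5 were lower in BCP among fragments of at most 20 nt and higher among those of at least 30 nt: trnC-GCA, trnF-GAA, trnN-GUU, trnR-UCU and trnV-GAC. The largest fall of short fragments was that of trnC-GCA, with 1269 UNM and 491 BCP reads of at most 20 nt (log2 ratio of shares -4.22) and 18 and 2784 reads of at least 30 nt (4.42). Of the 31 UNM sequences of 34 to 37 nt with at least 50 reads, 13 are absent from the BCP list, and all 13 are listed in TCP. The 35-nt Gly fragment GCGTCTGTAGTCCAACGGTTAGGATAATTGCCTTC had 2885 reads in UNM and 0 in BCP, where the fragment shorter by its last base had 24212. The lists also end with a gap: UNM holds 95 sequences and 544 reads of 40 nt and none of 38 or 39 nt, BCP 286 sequences and 28672 reads of 39 nt and none of 38 nt, and TCP 252 sequences of 40 nt, 1 of 38 nt and none of 39 nt.

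The rise of long fragments from UNM to BCP was weighed against technical explanations. A size selection or trimming step that acts on length alone is argued against as the whole cause, since at 33 nt, the length of the class with the most UNM reads, the log2 change differed between 10 amino acid groups with an SD of 1.58, from 0.46 for Cys to 6.19 for Phe. A length-dependent step stays open for the part shared by all groups, whose smallest log2 change at 30 to 34 nt was 1.04. At 34 nt alone Glu fell (-0.69), from 1461 UNM reads. These include sequences with 298 and 215 UNM reads that are absent from the BCP list, so that fall depends on what the lists hold. Random breakage of tRNAs in UNM stays open too. Of reads of at most 20 nt, 81.6% in UNM and 82.4% in BCP are placed at mature positions 1 to 3. Neither share counts 13-nt fragments that start at position 1, which the rule cannot place. A preparation that needs a 5′ phosphate could also favour 5′ fragments whatever broke the tRNA. The developmental stage may also account for the rise, and with 1 library per stage it cannot be told apart from the library.

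The higher share of plastid-type fragments was weighed in the same way. The shift to long fragments is argued against as the whole cause, since among fragments of at most 20 nt the plastid-type share went from 2.13% to 14.3%, a log2 ratio of 2.74, against 8.45% and 11.7% among those of at least 30 nt. Carry-over of plastid-rich tissue, such as anther wall, in the BCP fraction would raise plastid-type tRNAs together, and their log2 ratios had an SD of 1.86 over 17 tRNAs. Since the fragment profile of such tissue is not known, that spread cannot decide, and carry-over stays open, as does a difference between the stages, which could account for the rise but has 1 library per stage.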
